A study of Tursiops truncatus with 8 samples.

How the data were processed

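RNA from 8 cultured skin slices of a bottlenose dolphin was measured on 8 one-colour Agilent arrays, 1 array per culture condition. Per the labels' protocols, the slices were about 2 mm thick, held epidermis and dermis, came from a stranded animal and were kept for 24 h at 24 to 28 °C, and Cy3-labelled RNA was made from 0.5 µg of total RNA. Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, which subtracted the background and removed a spatial trend within each array. The deposited processed signal is an intensity on a linear scale, not normalized between arrays, and the authors' deposited table of the whole series holds the same intensity multiplied by 1000000 and rounded (log2 ratio to the scanner value between 19.92 and 19.94 in each column), with no centring and no change of direction. The medians of that table's columns, divided by 1000000, were 95.8 for medium, 104 for methanol, 96.05 and 60.45 for PFOA titled 1 and titled 0.1, 85.1 for ethanol, and 105, 80.6 and 59.2 for BPA 0.1, 1 and 100.

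Groups were taken from the sample titles. For PFOA (perfluorooctanoic acid) the title and the description of each of the 2 samples give opposite doses, so these arrays are called PFOA titled 1 and PFOA titled 0.1 and no order of dose was drawn from them. The titles give doses in mg/ml, whereas the treatment protocol in the labels gives 0.1 and 1 µg/ml for both compounds and does not list the 100 of the BPA (bisphenol A) title, so the numbers 0.1, 1 and 100 are used here as names of the arrays, without a unit. Nothing in the labels says that slices came from separate animals, so every p-value measures only the spread between slices and arrays, which may be technical. Per the file headers, the arrays lay on 2 slides scanned separately: medium, methanol and both PFOA arrays on slide 1, ethanol and the 3 BPA arrays on slide 2. Each exposed array was compared with its vehicle within a slide, whereas slide and vehicle cannot be told apart for ethanol against medium.

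Control spots and spots flagged as outliers were left out, log2 of the processed signal was reduced by the 75th percentile of its array, and the spots of a probe were averaged. The array held 43803 spots of 24418 probes, of which 21559 were named for assembled contigs, 2702 for single sequence reads, 137 by GI number and 20 for genes. None of the GI numbers was found in the reference gene table, and the files do not pair the contigs or reads with gene names, so probes are called features and most carry no gene name. The 20 named probes stand for 13 genes, 9 of whose symbols were found in the reference table without regard to letter case. A named gene was measured by its brightest probe, which left 24411 features. Of the 36 lists of genes and cell type markers fixed beforehand, with 716 symbols, 1 member was named on the array, the endothelial marker CDH5, which was not well above background on any array. No list reached 5 named members, so no list was tested. CYP1A1, ESR1, PPARA, PPARG and HSPA1A, fixed to be named whatever their values, are not named among the probes and were not analysed here.

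For each pair of arrays, features at least 2-fold apart were counted where the brighter array was well above background. Where the dimmer array was not, the fold is a bound against the higher of its own value and the lowest signal well above background on that array. With 1 array per condition these counts have no replicate check and no p-value. The tests were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05) on all 8 arrays in 5 classes: medium, methanol, PFOA, ethanol and BPA. The residual is the spread between arrays of different doses of a compound, with 3 residual degrees of freedom, or 2 for the slope on log10 of the BPA dose. A vehicle with 1 array was assumed to vary like them, and any effect of dose widens this spread. Features well above background on at least 2 arrays (18646) were tested, a filter chosen after the files were seen. All other choices of the main comparisons were made before the data were examined, except the counts of dose against dose and of exposed arrays against medium.

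The fits were tested on simulated data for the 18646 features with 200 changed by known amounts, 50 of each size. The noise was normal and independent, with feature variances drawn from the distribution that limma itself had fitted. It was equal on all arrays and held no slide or array effect, whereas the real arrays differed in scatter. Recovery and false calls thus apply only where the assumptions of the fit hold. For BPA exposure the fit recovered 1 of 50 at 2-fold, 33 of 50 at 4-fold, 50 of 50 at 8-fold and 49 of 50 at 16-fold, with 9 false calls. For PFOA exposure it recovered 0, 36, 50 and 50 of 50, with 4 false calls. For the difference between the compounds it recovered 0, 3, 23 and 45 of 50, with 5 false calls. The BPA dose slope gave 0, 9, 45 and 49 of 50, with 7 false calls. For the slope, the size is the whole change put in from BPA 0.1 to 100, not the change per 10-fold dose. Overlap of 2-fold features between arrays that share a vehicle was set beside 100 simulations without effect, whose noise was drawn from the difference between methanol and medium at like brightness. That difference can itself hold a vehicle effect. The simulations covered only the 16295 features well above background on all arrays, so they hold no bounds. Their lists were not matched in length to the real ones. Their noise source had an SD of 0.29 log2 units over features. The SD was 0.47 for BPA 100 against ethanol and 0.50 for PFOA titled 0.1 against methanol. An excess over the simulations can therefore also come from a noisier array.

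The rule fixed beforehand was to name genes with the same direction at every dose, those with the largest change from BPA 0.1 to 100, and those farthest from medium in each vehicle. It could be followed only in part. The 6 named genes well above background on all arrays are given whatever their direction, and the remaining named genes by their detection, a choice made after their values were seen. As most features have no gene name, only 4 of the unnamed features are given by probe, chosen from the ranked features or calls after their values were seen, and the features that rank highest against medium are otherwise not listed. Alternatives tried were normexp background correction with offset 50, on the median spot and background signals because no mean spot signal column was used, scaling to the median, quantile normalization, no filter on dim probes, the mean over a gene's probes, the deposited series table, an intensity trend with robust variance, the slide as a block with the 3 unexposed arrays as 1 class, and leaving out each exposed array. Added after the data were seen were a correction of blocks of 27 rows and 17 columns, cyclic loess, a demand that every spot be 2-fold apart, and fits without PFOA titled 0.1 and BPA 100. The number of arrays limits the precision.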

Results

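Gene expression was measured in slices of bottlenose dolphin skin kept in organ culture for 24 h with either of 2 contaminants, BPA, a plastics monomer, or PFOA, a perfluorinated surfactant. There was 1 array for each of 8 conditions: culture medium alone, methanol (the vehicle of PFOA), 2 PFOA cultures, ethanol (the vehicle of BPA) and BPA at titled doses of 0.1, 1 and 100. Between 69.6% and 77.4% of the 24411 features were well above background on each array, and no spot was saturated. Over the 16295 features well above background on all arrays, log2 values of any 2 arrays correlated with r from 0.980 to 0.996, across features, which are not independent replicates.

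The PFOA titled 0.1 and BPA 100 arrays were dimmer and noisier than the others. Their 75th percentile of processed signal was 400 and 387, against 527 to 704 on the other 6 arrays. The SD between duplicate spots was 0.38 log2 units on PFOA titled 0.1 and 0.22 on BPA 100, against 0.10 to 0.16 on the others. The median coefficient of variation in the file headers was 21.4% and 12.3% on these arrays, and 7.15% or less on the others. The quality summary in the file headers was in range on 3 arrays (medium, methanol and BPA 0.1) and marked for evaluation on the other 5, ethanol, the vehicle control of all BPA arrays, among them.

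**Figure D1:**
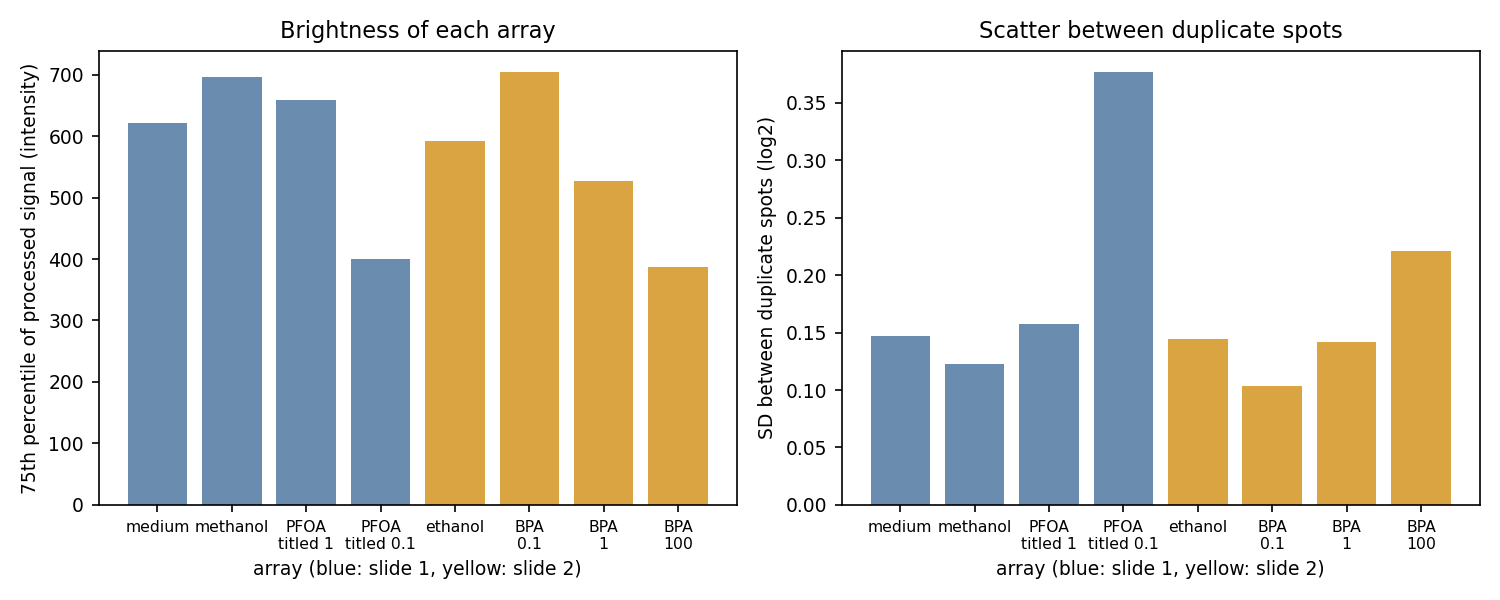
The left panel shows the 75th percentile of the processed signal (intensity) of each array, and the right panel the SD between duplicate spots (log2) over features with duplicate spots that were well above background on all arrays; bar colour marks the slide. PFOA titled 0.1 and BPA 100 are the dimmest arrays (400 and 387) and have the largest scatter (0.38 and 0.22).

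The comparison of BPA with ethanol asked how the skin transcriptome differed after exposure. Among the named genes well above background on all 8 arrays, HIF1a and HIF2a, transcription factors of the response to low oxygen, and MUC1, a cell surface mucin, read above ethanol at every BPA dose, though none passed the test. HIF1a was 1.14-fold, 1.34-fold and 1.45-fold of ethanol at 0.1, 1 and 100, and HIF2a 1.17-fold, 1.80-fold and 1.53-fold. Averaged over doses, HIF1a differed by 0.38 ± 0.27 log2 units (SE, 3 BPA arrays, limma adjusted p = 0.937) and HIF2a by 0.56 ± 0.33 (adjusted p = 0.937). The second HIF1a probe gave 0.59. Ethanol itself read low for these genes, at 0.787-fold of medium for HIF1a, 0.625-fold for HIF2a and 0.708-fold for MUC1. Against medium, MUC1 was lower at all 3 BPA doses, HIF2a at 0.1 and 100, and HIF1a at 0.1, so the direction depended on the control array. MUC1 differed by 0.31 ± 0.36 (adjusted p = 0.937), and its second probe, well above background on 7 arrays, gave -0.11. AbcA3, a lipid transporter of lung surfactant, was 1.27-fold and 1.36-fold of ethanol at 0.1 and 1 and 0.774-fold at 100. AQP5, a water channel, was 0.919-fold, 1.13-fold and 1.33-fold, and SFTPC, a surfactant protein, 0.960-fold, 1.03-fold and 1.09-fold. The second AQP5 probe, well above background on all 8 arrays, gave -0.18, against 0.16 for the brightest probe. Unscaled signals were 88.6 to 186 for HIF1a. They were 17.1 to 32.0 for SFTPC, 17.9 to 53.4 for AbcA3 and 19.0 to 35.7 for HIF2a. AQP5 read 25.6 to 76.8 and MUC1 33.4 to 56.6. Array medians were 64.6 to 114, so apart from HIF1a these genes were dim and their folds are uncertain.

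The number of features at least 2-fold from ethanol was larger at higher BPA doses, an order that did not hold against medium. At BPA 0.1, 136 of 18954 compared features were at least 2-fold apart, 61 higher and 75 lower. At BPA 1 there were 336, 265 higher and 71 lower, and at BPA 100 there were 735, 586 higher and 149 lower. For comparison, the unexposed pairs gave 359 features (methanol against medium) and 325 (ethanol against medium), so the counts at BPA 0.1 and BPA 1 were below or close to those between unexposed slices. Both pairs share the 1 medium array and set a vehicle against none, so they are not independent and may hold vehicle effects. The split of the BPA counts depended on scaling. With median scaling, quantile normalization and cyclic loess, BPA 1 gave 177 higher and 88 lower, 185 and 105, and 196 and 99. In the same order BPA 100 gave 426 and 258, 459 and 236, and 493 and 225, and BPA 0.1 gave 45 and 86, then 45 and 94, with cyclic loess within 10 points of the main split. At BPA 0.1 the split turned under normexp (13 higher and 4 lower) and with every spot 2-fold apart (8 and 6). Against medium, a control added after the data were seen, BPA 0.1 gave 244 features, BPA 1 gave 143 and BPA 100 gave 432. Of these, 41 were higher and 203 lower at BPA 0.1 (70 and 180 with quantile normalization, 79 and 189 with cyclic loess), 75 and 68 at BPA 1 (437 and 478 with no filter on dim probes, 6 and 14 with every spot 2-fold apart), and 270 and 162 at BPA 100 (18 and 45 under normexp).

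Lists from arrays that share ethanol overlap by construction. BPA 1 and BPA 100 shared 67 higher and 25 lower features, where simulations without effect gave means of 12.1 and 11.1 and independent lists would share 8.83 and 0.602. All 3 doses shared 6 higher and 19 lower features, where simulations gave 6.76 and 6.21, with maxima of 13 and 14, and independent lists 0.0308 and 0.00258. Well above background on all the arrays compared were 54 of the 67 and 5 of the 6 higher features, but 7 of the 25 and 4 of the 19 lower ones, so most shared lower features are bounds at background. The simulations hold no bounds, and 7 and 4 are below their means of 11.1 and 6.21. The simulated lists were not matched in length to the real ones, and overlap depends on length. The simulations therefore cannot decide whether the lower features hold an excess. With 1 ethanol array the control could not be split, and part of any excess may come from it.

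In limma's test over all BPA doses, no feature passed as higher and 1 of 18646 passed as lower, with 554 (2.97%) at an unadjusted p under 0.05. The feature that passed, probe AM-33378, is named for a single sequence read and has 1 spot on the array. It was at least 3.09-fold lower at each BPA dose (limma adjusted p = 0.00446), with a processed signal of 32.6 on ethanol and 2.67 or less on the BPA arrays. It was not well above background on any BPA array, so the size is a bound and the adjusted p rests on values at background. Its signal was 33.4 on medium but 3.48 on methanol and 1.74 and 0.874 on the PFOA arrays, so it was low on arrays without BPA as well. The call ended without the BPA 0.1 array (adjusted p of 0.0737 or more for any feature), under normexp, with no filter on dim probes, with cyclic loess and with slide as a block, and with an intensity trend and robust variance another feature passed in its place. Contig-c16945-1 (probe AM-19878, 2 spots) was among the features farthest above ethanol at every dose, by 2.49-fold or more (1.59 ± 0.36 log2 units, SE, limma adjusted p = 0.937). Its signal before scaling was 411 on ethanol, 667 to 1545 on BPA and 1985 on medium. After scaling it was below medium by 2.20 log2 units on ethanol. At BPA 0.1, 1 and 100 it was below medium by 0.54, 0.41 and 0.89.

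Across BPA doses, the limma slope on log10 dose passed for 0 features, with 1463 (7.85%) at an unadjusted p under 0.05. Under normexp 9 features passed, 8 rising with dose and 1 falling. All 9 had the same SE (0.116), so that fit gave these features a common variance. Their adjusted p therefore does not rest on the spread of each feature. Between arrays, BPA 100 against BPA 0.1 gave 554 features at least 2-fold higher and 113 lower, BPA 1 against BPA 0.1 gave 125 and 43, and BPA 100 against BPA 1 gave 184 and 106. With cyclic loess BPA 1 against BPA 0.1 gave 95 and 69. Under normexp BPA 100 against BPA 1 gave 8 higher and 15 lower, so that split turned. Of 17023 features well above background on the 3 arrays, 8122 (47.7%) moved in one direction through the doses, against 33.3% for orders drawn at random. That share also rises where the array at one end of the order is noisier, as BPA 100 was, and features are not independent of each other. Contig-c7480-1 (probe AM-10153) had the largest difference of 100 over 0.1 among features that moved one way, 5.23-fold, with signals of 1782, 3553 and 5138 (slope 0.75 ± 0.17 log2 units per 10-fold dose, SE, limma adjusted p = 0.624). Under normexp it had the smallest adjusted p of the 9 calls (slope 0.69, adjusted p = 5.1e-05), and over the alternatives the smallest adjusted p of the slope ranged from 5.1e-05 to 0.563. The same contig read 1703 on ethanol, 5444 on medium and 4710 and 5119 on the PFOA arrays. These signals are not scaled, whereas the folds are. After scaling, it was above medium by 0.60 log2 units at BPA 100 and 0.55 on PFOA titled 0.1. It was below medium at BPA 0.1 and 1 (-1.79 and -0.38), on PFOA titled 1 (-0.29) and on ethanol (-1.61).

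**Figure D2:**
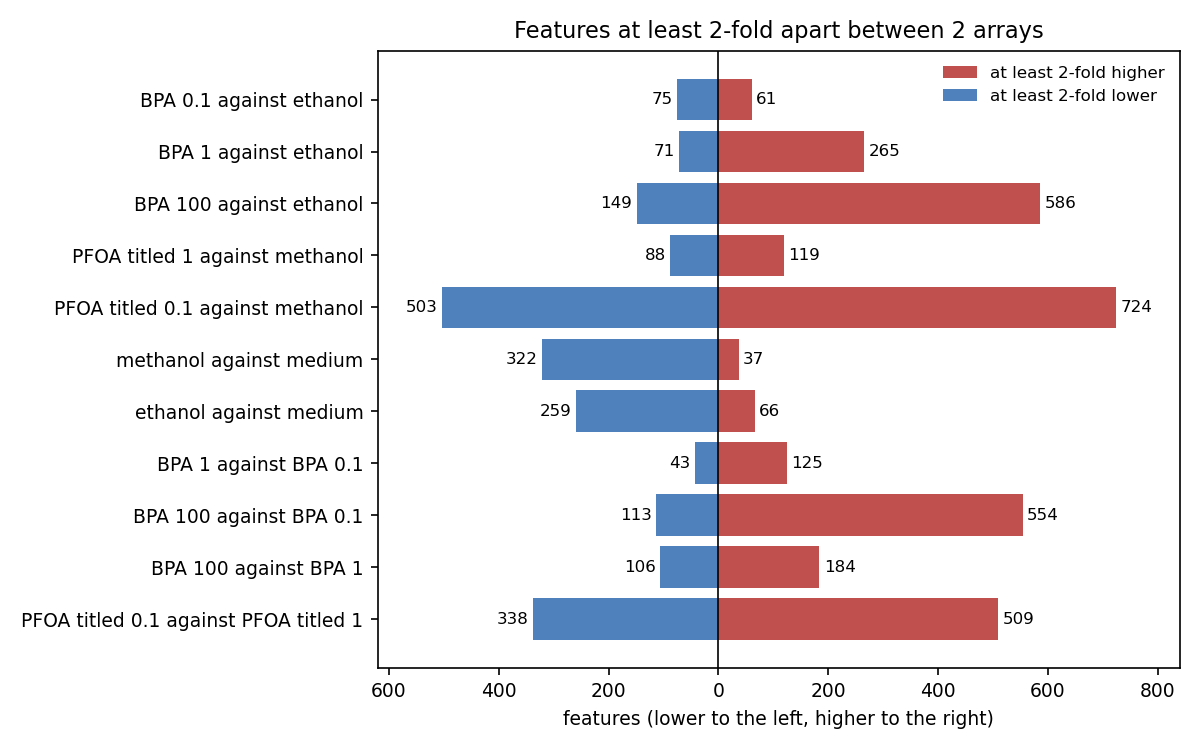
Bars show the number of features at least 2-fold higher (right, red) or lower (left, blue) in the first-named array than in the second, on log2 signals scaled to each array's 75th percentile, with 1 array per condition. PFOA titled 0.1 against methanol gave the most (724 and 503), and 2 pairs of unexposed arrays, both with medium as the control, gave 359 and 325 in all.

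The comparison of PFOA with methanol asked the same of PFOA. AQP5 was 0.463-fold of methanol on PFOA titled 1 and 0.911-fold on titled 0.1, HIF1a 0.693-fold and 0.809-fold, and HIF2a 0.655-fold and 0.935-fold. AbcA3 was 1.02-fold and 2.62-fold, MUC1 1.07-fold and 2.02-fold, and SFTPC 0.990-fold and 1.83-fold, so the larger values came from the noisier PFOA titled 0.1 array. Methanol itself read low for these genes, at 0.599-fold of medium for AbcA3, 0.799-fold for MUC1 and 0.516-fold for SFTPC. Against medium, SFTPC was lower on both PFOA arrays. AbcA3 and MUC1 were lower than medium on PFOA titled 1 and higher on titled 0.1. AQP5, HIF1a and HIF2a were lower than medium on both. None passed limma's test over both arrays: AQP5 differed by -0.62 ± 0.42 log2 units (SE), AbcA3 by 0.71 ± 0.55, MUC1 by 0.56 ± 0.38 and HIF1a by -0.42 ± 0.28, each with an adjusted p of 0.988. Probes of a gene disagreed for AQP5, whose second probe gave 0.32, and for HIF1a, whose second probe gave 0.09. Under normexp the AQP5 and HIF2a differences changed sign, to 0.014 and 0.24. The duplicate spots of AQP5 differed widely, with an SD of 1.77 log2 units on methanol.

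**Figure D3:**
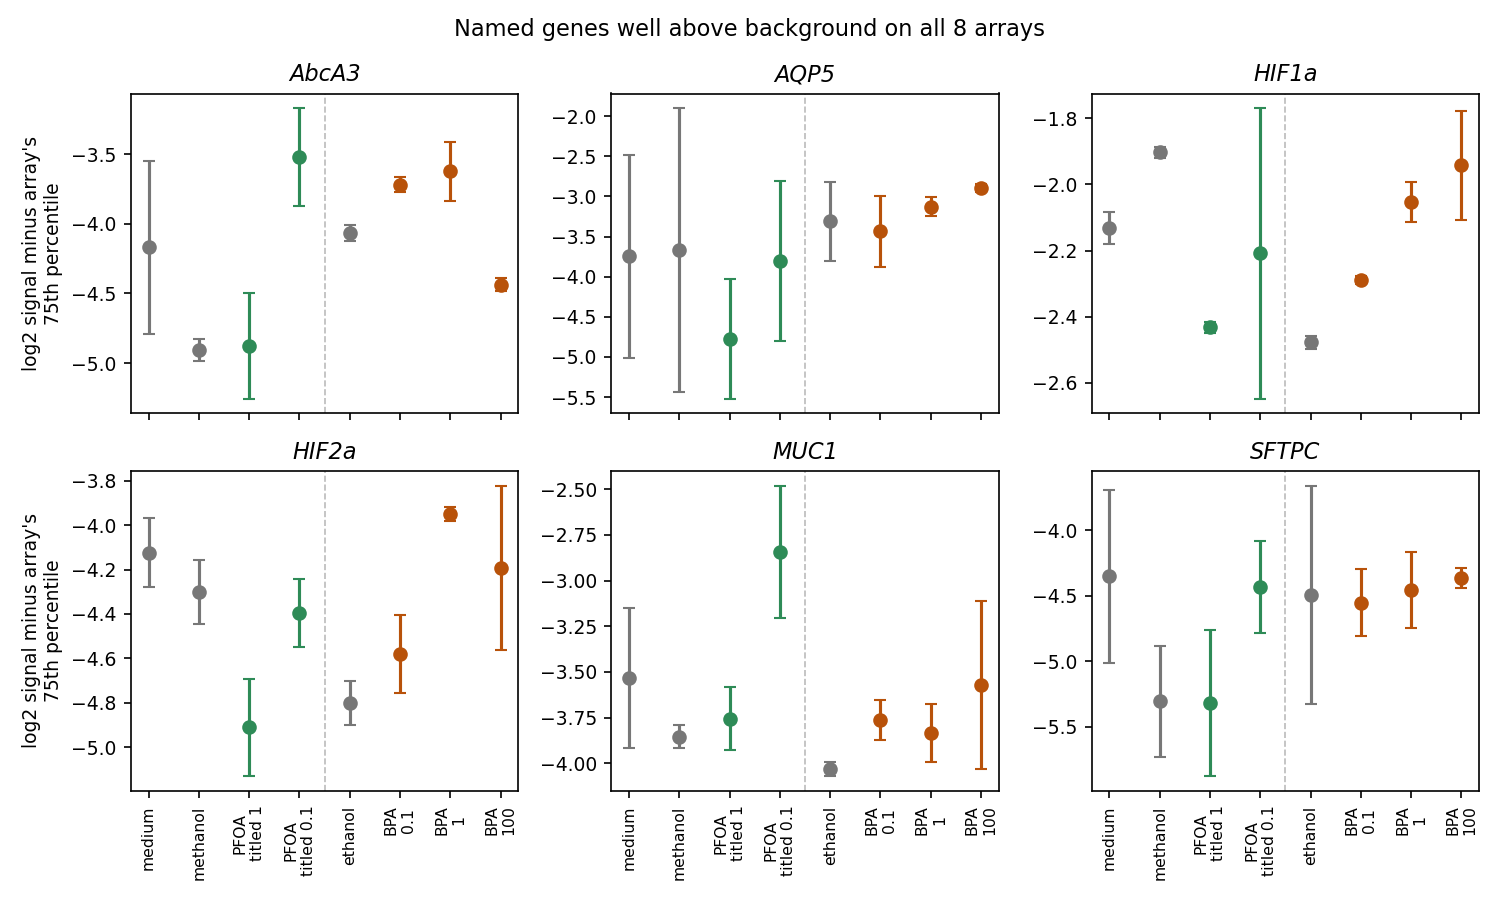
Points show log2 signal minus the array's 75th percentile for the 6 named genes well above background on all 8 arrays, bars are the SD between duplicate spots within the array (not between animals), and the dashed line parts slide 1 (left) from slide 2; grey is unexposed, green PFOA and orange BPA. HIF1a read -2.48 on ethanol and -2.29, -2.05 and -1.94 at BPA 0.1, 1 and 100, and MUC1 was highest on PFOA titled 0.1 (-2.84).

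PFOA titled 1 gave 207 features at least 2-fold from methanol of 18280 compared, 119 higher and 88 lower, fewer than the 359 between methanol and medium. PFOA titled 0.1 gave 1227 of 18343, 724 higher and 503 lower. With quantile normalization the splits were 131 and 55 for titled 1, and 602 and 636 for titled 0.1, where lower features then outnumbered higher ones. Under normexp titled 0.1 gave 246 higher and 299 lower. With no filter on dim probes titled 1 gave 440 and 516, and titled 0.1 gave 2422 and 760. PFOA titled 0.1 against PFOA titled 1 gave 509 higher and 338 lower. It gave 341 and 480 with quantile normalization, 358 and 466 with cyclic loess and 56 and 230 under normexp, but 1747 and 529 with no filter. Against medium, a control added after the data were seen, titled 1 gave 43 higher and 199 lower, and titled 0.1 gave 292 and 539. Both main splits thus turned with the control. With no filter, titled 0.1 against medium gave 1469 and 874. Against methanol, the 2 PFOA arrays shared 47 higher and 36 lower features, where independent lists would share 4.83 and 2.48. Well above background on all the arrays compared were 38 of the 47 and 10 of the 36. Simulations without effect, which hold no bounds and were not matched to the length of these lists, gave 10.99 and 11.46. They therefore cannot decide whether the lower features hold an excess. Part of any excess of higher features may come from the shared methanol array or from the noisier PFOA titled 0.1 array. Limma's test over both arrays passed 0 features (smallest adjusted p = 0.146), with 824 (4.42%) at an unadjusted p under 0.05. It passed 1 feature with quantile normalization, 1 with slide as a block, and 1 without the PFOA titled 1 array. Contig-c25460-1 (probe AM-28191, 1 spot) was lowest relative to methanol, by 22.3-fold on PFOA titled 1 and at least that on titled 0.1, where it was not well above background (limma adjusted p = 0.260). Its signal was 231 on methanol but 17.9 on medium and 14.2 on ethanol, against 9.78 and 2.94 on the PFOA arrays.

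The difference between the BPA and PFOA effects was tested directly. HIF1a differed by 0.80 ± 0.39 log2 units (SE, limma adjusted p = 0.852) and HIF2a by 0.91 ± 0.48 (adjusted p = 0.853), with higher values under BPA, so the difference did not pass for either gene. The signs under the 2 compounds were opposite by these probes, but the second HIF1a probe read above the vehicle under both (0.59 and 0.09), and so did HIF2a under normexp (0.39 and 0.24). Limma passed 0 of 18646 features, with 1072 (5.75%) at an unadjusted p under 0.05, and 1 under normexp, Contig-c16945-1. The doses averaged for the 2 compounds were not matched, since BPA includes 100. The PFOA labels conflict only in order, as title and description both give 0.1 and 1. Without the BPA 100 array limma also passed 0 features for this difference (smallest adjusted p = 0.384).

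The vehicles were compared with medium to give the background between unexposed slices, though both comparisons use the 1 medium array and may hold a vehicle effect. On methanol and ethanol in turn, SFTPC was 0.516-fold and 0.908-fold of medium, AbcA3 0.599-fold and 1.07-fold, HIF1a 1.17-fold and 0.787-fold, HIF2a 0.884-fold and 0.625-fold, MUC1 0.799-fold and 0.708-fold, and AQP5 1.06-fold and 1.35-fold. Methanol against medium, both on slide 1, gave 37 features at least 2-fold higher and 322 lower, or 63 and 230 with quantile normalization. Ethanol against medium, on different slides, gave 66 and 259, with 94 and 161 under median scaling, 127 and 171 under quantile normalization and 95 and 194 under cyclic loess. Of the 2-fold features, 10.3% were higher than medium on methanol, 20.3% on ethanol and 16.8% at BPA 0.1. The share was 17.8% on PFOA titled 1 and 35.1% on titled 0.1, but 52.4% at BPA 1 and 62.5% at BPA 100. The medium array may therefore contribute to these splits. Asked of the same limma fit after the data were seen, methanol against medium passed 0 features (507 at an unadjusted p under 0.05), ethanol against medium 0 (620) and ethanol against methanol 1 (959).

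Of the other named genes, CC10, a secreted airway protein, was well above background on 3 arrays by its brightest probe and on 7 by its second probe, which gave 0.57 log2 units for BPA over ethanol and -0.15 for PFOA over methanol. NKX2-1, a lung and thyroid transcription factor, was well above background on 2 arrays and FOXF1 on 1. CDH5, PDPN, SFTPA1 and SFTPB were not well above background on any array, which leaves no fold for them.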

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

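Block correction, cyclic loess, the demand on every spot and the fits without 2 arrays were chosen after the data were seen, as were the comparisons of dose with dose. Median scaling, quantile normalization and cyclic loess kept each count against a vehicle or between doses within 1.5 times its main value; the splits that moved are given with the comparisons. Normexp moved the median log2 difference of a comparison by -0.07 to 0.26, and the other settings by up to 0.13 in size. The 2-fold counts changed with how background and dim probes were treated and with the demand on every spot. Of the 2-fold features with several spots, 23.3% to 49.2% met that demand in these comparisons. The cause of the changes in counts was not tested.

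In the order BPA 0.1, 1 and 100 against ethanol, PFOA titled 1 and titled 0.1 against methanol, methanol and ethanol against medium, the totals were 136, 336, 735, 207, 1227, 359 and 325. Under normexp they were 17, 76, 164, 39, 545, 119 and 70. With no filter on dim probes they were 1039, 1215, 1788, 956, 3182, 1245 and 1302. With every spot 2-fold apart, which only features with several spots can meet, they were 14, 67, 209, 33, 273, 76 and 67. For BPA 1 and 100 against 0.1, BPA 100 against 1, and PFOA titled 0.1 against titled 1, the totals of 168, 667, 290 and 847 became 26, 190, 23 and 286 under normexp, 1112, 3519, 1202 and 2276 with no filter, and 26, 210, 44 and 178 with every spot 2-fold apart.

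The BPA call in limma's test (1 feature) went to 0 under normexp (smallest adjusted p = 0.285), no filter (0.0870), cyclic loess (0.0817) and slide as a block (0.138), and leaving out each BPA array gave 0 to 1. The PFOA count of 0 became 1 with quantile normalization (adjusted p = 0.00601) and with slide as a block (0.0184), and leaving out each PFOA array gave 0 to 1. Leaving aside the fit without PFOA titled 0.1 and BPA 100, the smallest adjusted p for BPA ranged from 0.00234 (median scaling) to 0.285 (normexp). For PFOA it ranged from 0.00601 (quantile normalization) to 0.450 (no filter). The difference between compounds became 1 and the dose slope 9 under normexp (smallest adjusted p of 0.00360 and 5.1e-05). The 9 slope calls had a common SE, not one from the spread of each feature.

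Without PFOA titled 0.1 and BPA 100, limma called 335 features for BPA, 291 for PFOA and 656 for their difference. This fit has 1 residual degree of freedom, from BPA 0.1 and BPA 1, and it also called 446 features between methanol and medium, 445 between ethanol and medium and 843 between the vehicles. Its calls therefore do not by themselves mark exposure, since they cannot be told from differences between unexposed arrays. AQP5 for PFOA, then from 1 PFOA array, was -1.11 log2 units in it.

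Some named genes changed sign, among them genes whose PFOA values were not near 0 (AQP5 -0.62, HIF2a -0.35 and SFTPC 0.43). AbcA3 for BPA was -0.011 without BPA 1, and up to 0.40 without each other BPA array. AQP5 for BPA was -0.0090 with the mean over probes. AQP5 and HIF2a for PFOA were 0.014 and 0.24 under normexp. SFTPC for BPA was -0.032 with median scaling, -0.081 with quantile normalization, -0.084 with cyclic loess, -0.0098 without the 2 noisier arrays, and from -0.0098 (without BPA 100) to 0.084 with each BPA array left out. SFTPC for PFOA was -0.048 with slide as a block, -0.015 without the 2 noisier arrays, and from -0.015 (without PFOA titled 0.1) to 0.87 with each PFOA array left out. No test of gene lists was run under any setting, since no list had enough named members. No paired analysis was possible because each condition has 1 array and the labels give no replicate numbers.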

Other observations

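The tests in this part were chosen after the results were seen, apart from the spike-in test, whose expected result was set before its values were computed. The rule for the ethanol array was rewritten several times with its values known, and under some versions BPA 100 was held to argue against it. The spike-in test was run with 2 choices of comparison and 2 sets of spike probes. Features are not independent replicates.

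More features were 2-fold higher than lower at BPA 1 and at BPA 100 against ethanol, and the ethanol array standing apart is a candidate explanation. The 265 features higher at BPA 1 kept a share of 0.296 of their median difference over medium and 0.562 over BPA 0.1, and the 586 at BPA 100 kept 0.599 and 0.863, though features picked for low ethanol values lose, and those picked on a noisy array keep, part of it by chance. Over all features and without the ethanol array, BPA 100 against BPA 0.1 gave 554 higher and 113 lower (75.04% or more higher under every setting), and BPA 1 against BPA 0.1 gave 125 and 43 (57.7% or more), so higher features outnumbered lower ones without that array too. Of the unexposed pairs, methanol against medium gave 37 and 322, a more uneven split than BPA 100 in all but 1 of 10 settings and than BPA 1 in all, while ethanol against medium, which holds the array in question, gave 66 and 259, less uneven than BPA 100 in 8 settings and than BPA 1 in 3. Both pairs share the medium array, so they are not independent. Against medium BPA 100 gave 270 and 162 but 18 and 45 under normexp, so the ethanol array, the BPA 100 array, differences between slices and a response to BPA may each contribute and cannot be told apart with 1 array each.

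PFOA titled 0.1 gave 1227 features 2-fold from methanol and PFOA titled 1 gave 207. Block correction left 1072 features, which argues against uneven hybridisation over areas as large as the blocks as the whole cause. Scatter between duplicate spots alone would not be shared by both spots, yet the spread shared by duplicate spots was 1.48 times as large for PFOA titled 0.1 (0.40 log2 units) as for titled 1 (0.27). A difference between the RNA samples, in dose or in quality, may remain, and these values do not separate them.

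The differences BPA 100 minus BPA 0.1 and PFOA titled 0.1 minus PFOA titled 1, which share no array, correlated with r = 0.453 across 16295 features (rho = 0.447), and r was 0.434 after cyclic loess and 0.513 after block correction, which argues against scaling that depends on brightness and unevenness at shared positions as the whole cause. A weaker scan or hybridisation of both arrays remains open: spike-in probes were dimmer by 0.726 of the dolphin shift on BPA 100 and 0.376 on PFOA titled 0.1 against the arrays of the pattern, by 0.906 and 0.774 against the other 3 arrays of the slide, and by as little as 0.349 with all spike probes, so the answer depended on the choice of comparison. Each array was scaled before r was computed, which removes an even dimming. This ratio of mean shifts therefore cannot decide whether a weaker scan bears on r. A shared response to a higher exposure is also open, if the description and not the title gives the PFOA dose. Among 210 pairs of differences that share no array, 8 had an r of at least this size, the observed one included, with a median size of 0.160 and a largest of 0.527; 4 of the other 7 again hold both PFOA titled 0.1 and BPA 100, and 3 do not. Other relations that share no array went both ways, with r of -0.433 for BPA 1 over ethanol and PFOA titled 1 over methanol, 0.293 for BPA 100 and PFOA titled 0.1 over their vehicles and -0.108 for the mean effects, so the design cannot decide between a shared response and a property of these RNA samples.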
